A study of Mus musculus with 4 samples.

How the data were processed

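Gene expression was measured on 4 oligonucleotide arrays of mouse RNA, 1 each from d/d heart, f/f heart, d/d muscle and f/f muscle. Per the labels, d/d mice carry a deletion of the MnSOD gene (Sod2) made by an MCK-Cre transgene, and f/f mice carry the floxed gene and serve as controls. The groups were taken from the sample titles and the tissue label. Each group holds 1 array, so there are no replicates, and no error between animals could be given. The labels do not say whether a heart and a muscle came from the same animal, nor how many animals a sample pools, and they do not name the muscle that was taken.

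The deposited table holds 1 linear intensity per probe set and array, for 45101 probe sets, of which 64 are array controls. How the authors made these intensity values from the scans, and to what target they scaled them, is not given in the sources used here. The deposited values run from 0 to 9375, and the 2% trimmed means of the arrays were 66.6 for d/d heart, 69.2 for f/f heart, 48.2 for d/d muscle and 51.4 for f/f muscle, so the arrays had not been brought to 1 common mean over these probe sets. The highest value was between 8460 and 9375 on each array. The values carry no detection call, so signal near the background had to be handled by a floor.

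Each array was multiplied to bring its 2% trimmed mean to the mean of the 4, control probe sets left out. Signals under a floor were then set to the floor, 7.51, the mean over the arrays of the 40th percentile, and log2 was taken. Of the probe sets, 58.0% on the d/d heart array, 61.1% on the f/f heart array, 60.6% on the d/d muscle array and 60.3% on the f/f muscle array lay above the floor. Probe sets were named through the platform annotation given for this work, with symbols looked up through the Entrez id in a RefSeq gene table. Of 45037 probe sets, 34945 had 1 gene symbol, 932 had several and were named for none, and 9160 were not listed and are unnamed here. The lookup found 34741 ids and changed 0 symbols. A gene was represented by its probe set with the highest mean log2 signal, which gave 18193 genes. Of the named genes with several measured probe sets, 39 of 83 in heart and 34 of 67 in muscle had another probe set that differed by over 1.5 times from it. For 18 in heart and 29 in muscle another probe set differed in the other direction. Of those past 2-fold, 23 of 38 in heart and 17 of 20 in muscle had another probe set under 2-fold.

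A gene was counted as higher or lower when it differed by 2-fold or more and the higher array was above the floor. Where the lower array was at the floor, the fold is a lower bound and is written as such. As a technical yardstick, the SD of the log2 difference between probe sets of the same gene was 0.388 in heart, over 5375 genes, and 0.400 in muscle, over 5207 genes. It measures disagreement between probes, not variation between animals.

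Before the data were examined, 45 gene lists were fixed from general knowledge of metabolism, stress responses, muscle, the heart and the cell types these tissues hold. They have 949 entries, of which 861 matched a gene on the arrays. For each list with 4 or more measured members the median log2 difference was taken, with a 95% interval from order statistics over the genes, and set against 10000 random lists of the same size matched on mean level in 20 bins. A list is said to stand apart below the 2.5th or above the 97.5th percentile. The genes of a list are not independent replicates, and the percentile describes these arrays only. In a check on simulated data for the heart comparison, lists of 20 genes were drawn at random from 13836 genes. They stood apart in 3% of 100 draws with no shift added and in 98% with 0.5 added. Lists drawn this way hold unrelated genes, so the 3% does not carry over to lists whose genes vary together. Muscle was not checked.

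The genotype effect averaged over heart and muscle was fitted with limma, tissue as a block, over 13497 genes above the floor on at least 2 arrays, with Benjamini-Hochberg adjustment at 0.05. This leaves 1 residual degree of freedom and takes any difference between the tissues as error. On simulated data for this comparison, over the same 13497 genes and 10 simulations, the fit recovered 0% of genes changed by 1 on the log2 scale, 30.2% of those changed by 2 and 96.3% of those changed by 3. False calls made up 11.3% of calls at a change of 2 and 7.85% at a change of 3. At a change of 1 all calls were false, with a mean of 0.2 per simulation. Concordance between the tissues was described by correlations across genes and by the overlap of the lists of genes past 2-fold.

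The genes named were chosen by a rule fixed before the data were examined. It takes Sod2 with all its probe sets. For each tissue it takes the 10 genes most raised and the 10 most lowered among those at least 2-fold different with both arrays above the floor and all measured probe sets on the same side, and the 3 largest lower bounds per direction. The rule adds, among genes above the floor on all 4 arrays and with all measured probe sets on the same side in each tissue, the 10 with the largest difference shared by both tissues, and up to 5 that differ 2-fold in opposite directions. For these shared and opposite genes the condition on probe sets was carried over from the rule for single tissues, whose wording does not state it for them. It also takes up to 4 members of each list, and Nppa, Nppb, Myh6, Myh7 and Atp2a2 in heart. A few further genes are named as chosen after their values were seen.

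The alternatives were quantile normalization over the 4 arrays, removal of a loess trend with level within each tissue (span 0.4), floors at the 20th and 60th percentiles, log2 of the value plus the floor, the median over a gene's probe sets, leaving out probe sets whose suffix marks possible shared sequence, a 3-fold threshold, and an intensity trend in the limma fit. After seeing the data, a floor at the 75th percentile was added, as were counts without genes at least 8-fold higher in the other tissue. The work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9, and in R 4.3.3 with limma 3.58.1.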

Results

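The series compared the transcripts of heart and muscle from mice labelled as MnSOD-deficient in these tissues (d/d) with those of control mice (f/f). MnSOD, the product of Sod2, converts superoxide to hydrogen peroxide in mitochondria. The d/d tissue was compared with the f/f tissue in heart and in muscle, and these differences were then set against each other. Each of the 4 groups had 1 array, with 58.0% to 61.1% of probe sets above the floor, so every difference describes a pair of arrays. The arrays of a tissue resembled each other, with a Pearson correlation of 0.960 across probe sets for the heart pair and 0.975 for the muscle pair, against 0.868 to 0.888 between tissues. Xist, transcribed from the inactive X chromosome, was above the floor on all 4 arrays, at 169 to 368, and the Y-linked genes Eif2s3y and Uty were at the floor on all 4, while Kdm5d read 8.42 in f/f heart and was at the floor on the others.

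Sod2 transcript was lower in d/d heart on each of its 4 probe sets, by a mean of -0.62 on the log2 scale (SD 0.47 between probe sets). The brightest probe set read 1927 in d/d heart and 2330 in f/f heart, a log2 difference of -0.27, while the dimmest read 29.2 and 67.8, a difference of -1.22. The other probe sets differed by -0.21 and -0.79. In muscle 3 of the 4 probe sets were lower in d/d, and the mean difference was -0.21 (SD 0.21), with single values from -0.44 to 0.06. Where the probe sets lie relative to the deleted part of the gene is not stated in the sources used here, and a probe set outside that part does not check the genotype.

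**Figure D1:**
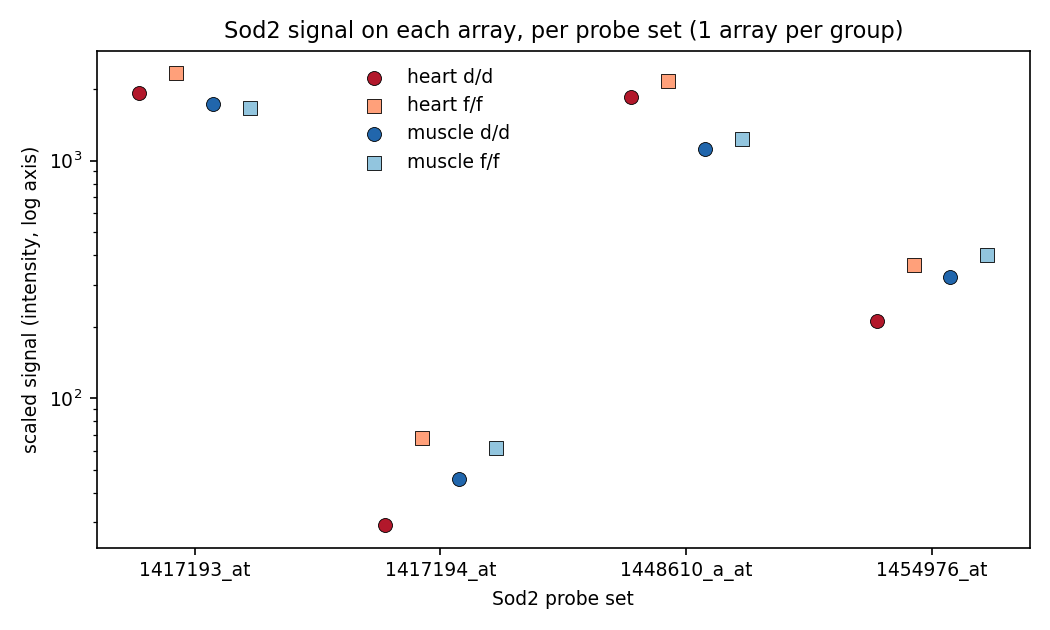
Scaled signal (intensity, log axis) of the 4 Sod2 probe sets on each of the 4 arrays, 1 point per array. The d/d heart point lies below the f/f heart point for each probe set, from 29.2 against 67.8 to 1927 against 2330, and the muscle points lie closer together.

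In d/d heart, genes of the extracellular matrix and of the heart failure and fetal program were higher than in f/f heart, and genes of fatty acid use and a list of adult cardiac genes known to decline in heart failure were lower. The matrix list had a median log2 difference of 1.27 (interval 0.93 to 1.70), with 22 of 37 members at least 2-fold higher, 0 at least 2-fold lower, and 0 of 10000 random lists reaching that median. Thbs4, a matrix glycoprotein, was 13.5-fold higher, Lox, which cross-links collagen, 11.6-fold and 6.69-fold on its 2 probe sets, the collagen gene Col8a1 8.38-fold, and the protease inhibitor Timp1 read 193 against 19.2. Nmrk2, a nicotinamide riboside kinase that makes NAD precursors, was 46.6-fold higher, at 2041 against 43.8. The fatty acid list had a median of -0.58 (interval -0.86 to -0.26), with 28 of 29 members below 0 and 7 at least 2-fold lower.

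Of the heart failure and fetal program, 11 of 22 members were at least 2-fold higher and 1 was lower, with a median of 1.04 (interval 0.18 to 1.64). Besides Nmrk2, these included Postn, 6.51-fold higher, and the matricellular gene Ccn2, 5.46-fold. Postn, Ccn2 and Timp1 are also on the matrix list, so the rises of these lists are in part the same result. Nppb, which encodes the B-type natriuretic peptide, read 4873 in d/d and 1945 in f/f heart, 2.51-fold higher, and Nppa was 1.85-fold higher. Myh7, the fetal myosin heavy chain of the mouse ventricle, was 3.47-fold higher and skeletal actin Acta1 3.11-fold. The adult myosin Myh6 and the calcium pump Atp2a2 differed by -0.07 and -0.10 on the log2 scale, within the spread of 0.388 between probe sets of a gene, although both were near the top of the signal range. Dimmer probe sets were lower, the other of Myh6 at 514 against 1231, a difference of -1.26, and those of Atp2a2 by up to -1.24.

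Among the 10 genes with the highest d/d to f/f ratio in heart were also Comp at 18.3-fold, Cilp at 15.5-fold, Ccn5 at 13.2-fold and Ltbp2 at 12.1-fold. The protease inhibitor Serpina3n was 15.3-fold higher and galectin-3, Lgals3, 11.6-fold. Against an f/f signal at the floor, the microfibril gene Mfap4 was at least 57.1-fold higher, Tnmd, a tendon gene, at least 14.0-fold, and the NADPH oxidase gene Nox4 at least 13.0-fold, or at least 5.06-fold on its other probe set. Mthfd2, a mitochondrial enzyme of one-carbon metabolism, was 12.2-fold higher on the probe set that represents it and 3.02-fold on the other. It belongs to the integrated stress response list, of which 7 of 32 members were at least 2-fold higher and 0 lower, with a median of 0.36 (interval -0.03 to 0.82; 99.98th percentile). Others of that list were Nupr1, 5.29-fold higher, the asparagine synthetase gene Asns, 3.65-fold, and the amino acid transporter Slc7a5, at least 4.32-fold.

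Among the genes with the lowest d/d to f/f ratio in heart, the carboxylesterase Ces1d was 13.9-fold lower, at 25.5 against 354, the mitochondrial carrier Ucp3 13.5-fold (35.5-fold on its other probe set), the acyl-CoA thioesterase Acot1 8.01-fold, and the gluconeogenic enzyme Fbp2 6.94-fold. Of the fatty acid list, the peroxisomal enzyme Ehhadh was 3.56-fold lower and the lipase inhibitor Angptl4 3.23-fold. Car3, a carbonic anhydrase, was 6.64-fold lower (3.19-fold and 1.53-fold on its other probe sets), followed by 2210407C18Rik at 6.14-fold, Tbc1d10c at 5.77-fold, the ephrin Efnb3 at 5.51-fold, Retnla at 5.30-fold and the amylase Amy1 at 5.29-fold. With the d/d signal at the floor, Tigd5 was at least 6.03-fold lower (1.14-fold on its other probe set), the enkephalin gene Penk at least 5.54-fold and the granzyme Gzmm at least 5.43-fold. The transcriptional regulators of mitochondria Ppargc1a and Ppara were 1.80-fold and 1.75-fold lower, short of 2-fold, with 1.17-fold to 1.44-fold on the 4 other probe sets of Ppargc1a and 2.12-fold and 2.32-fold on the 2 others of Ppara.

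Adult cardiac genes known to decline in heart failure had a median of -0.52 (interval -1.04 to -0.10), with 7 of 21 at least 2-fold lower and 0 higher. Adra1b, an adrenergic receptor, was 4.49-fold lower, the potassium channel genes Kcnv2 and Kcnj3 2.80-fold and 2.43-fold, and Kcnj2 at least 2.73-fold. Kcnj3 is also on the list of atrial markers, which had a median of -0.68 in heart. The calcium handling list had a median of -0.36 (interval -0.74 to -0.01), with 6 of 30 at least 2-fold lower and 1 higher. It shares Ryr2, Atp2a2, Pln and Hrc with the adult cardiac list and Atp2a1, Casq1 and Pvalb with the fast fibre list, so it is not a separate result. The gene that was higher, Cacnb1, was 3.06-fold higher on the probe set that represents it and 2.14-fold lower on a dimmer one. Ryr2, the calcium release channel of the heart, was 2.24-fold lower, the kinase gene Camk2a 2.47-fold (1.02-fold to 4.58-fold on dimmer probe sets) and Jph1 2.26-fold. For oxidative metabolism the shifts were small: complex I had a median of -0.17, with 31 of 34 members below 0, and the tricarboxylic acid cycle -0.21, with 20 of 23 below 0, and 0 members of either passed 2-fold. Complexes II, III and IV and ATP synthase had medians of -0.18, -0.19, -0.11 and -0.12 and did not stand apart, nor did the mitochondrial chaperones at -0.18. The mitochondrial biogenesis list, at -0.12, stood apart only with the median over a gene's probe sets, at -0.22.

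Antioxidant enzymes in heart had a median of 0.09 (interval -0.09 to 0.33), which did not stand apart, except with the median over a gene's probe sets. Only Srxn1, a sulfiredoxin, passed 2-fold among the 31 members, at 2.01-fold higher, with 2 of its other probe sets at 2.27-fold and 2.82-fold higher and another, near the floor, 1.95-fold lower. The NRF2 and glutathione list had a median of 0.02, with Nqo1 1.82-fold higher and Gstk1, a mitochondrial and peroxisomal glutathione transferase, 3.68-fold lower. The p53 and cell death list (0.16), cytosolic heat shock proteins (0.17), interferon-responsive genes (-0.12), atrophy genes (-0.01), immediate early genes (-0.10), glycolysis (-0.0004), clock genes (0.18), and iron and haem (-0.07) did not stand apart. Of these, the heat shock list stood apart under 4 of 9 settings and the p53 and immediate early lists under 1 of 9 each, and the clock median ran from -0.29 to 0.19 over the settings. Ribosomal protein genes had a median of 0.01, which was -0.05 without probe sets that can share sequence, and housekeeping genes 0.02.

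Markers of other cells also differed in heart. Macrophage markers had a median of 0.59 (interval 0.37 to 0.89), with 17 of 18 above 0. Ctss and Cx3cr1 were 2.97-fold and 2.90-fold higher, the latter 1.15-fold lower on a dimmer probe set, and Cd163 was 2.46-fold lower. Fibroblast markers had a median of 0.48 (interval 0.08 to 1.12), with Col1a2 3.26-fold and Col1a1 3.08-fold higher, both also on the matrix list. The 9 fibroblast markers outside that list had a median of 0.24 (interval -0.08 to 0.90). Endothelial markers had a median of 0.32 (interval -0.03 to 0.49) and cell cycle genes of 0.54 (interval 0.14 to 0.99). The macrophage, fibroblast, endothelial and cell cycle lists all stood apart on the high side. On the low side stood atrial markers (interval -1.28 to 0.0001), with Bmp10 3.11-fold lower, adipocyte markers at -0.42 (interval -1.39 to 0.60), with Adipoq 4.47-fold lower, fast fibre genes at -0.70 and skeletal muscle markers at -0.45. The last 2 lists had low signals in heart, such as 20.9 against 55.4 for Mybpc2. The 3 control probe sets for the small ribosomal RNA were higher on the d/d heart array, by 1.82-fold, 2.58-fold and 1.64-fold, and the 45 spike-in probe sets had a median ratio of 1.229, against 0.9285 in muscle, with 40 and 13 of them above 1. Lymphocyte (0.02), neutrophil (0.03), red cell (-0.16), smooth muscle (0.15), nerve (0.12), ventricular (-0.22), slow fibre (-0.03), cardiac (-0.10) and muscle regeneration (-0.14) lists did not stand apart, except without probe sets that can share sequence, where the nerve list was at 0.81 and the regeneration list at -0.35. With the floor at the 60th percentile the regeneration median was 0.09.

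Of 13836 genes measured in heart, 545 were at least 2-fold higher in d/d and 584 at least 2-fold lower, 127 and 201 of them as lower bounds. At 3-fold 149 were higher and 112 lower. With the floor at the 60th percentile, 320 and 249 genes passed 2-fold. Of the lists, 7 stood apart on the high side and 9 on the low side. For lists of unrelated genes 2.15 of the 43 evaluated would stand apart. The lists used here share members, and the genes of a list can vary together, so that number is not a chance level for them. The positions of complex I and adipocyte lists were lost under 2 of 9 settings and those of the tricarboxylic acid cycle, endothelial, skeletal muscle and cell cycle lists under 1 of 9.

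In d/d muscle, genes usually found in cardiac muscle, matrix genes and immediate early genes were lower than in f/f muscle. Tnni3, cardiac troponin I, was 10.5-fold lower, at 8.30 against 86.8, the muscle LIM protein gene Csrp3 7.95-fold, at 249 against 1979, and cardiac myosin-binding protein Mybpc3 4.61-fold. Cardiac markers had a median of -0.88 (interval -2.05 to -0.01), with 8 of 16 measured members at least 2-fold lower and 0 higher. Slow fibre genes, some of which are also cardiac genes, had a median of -0.65 (interval -1.87 to -0.19), with 5 of 14 at least 2-fold lower. Among them were the myosin light chain Myl2, 4.04-fold lower, sarcolipin, Sln, 3.66-fold, and Myoz2, 2.86-fold. Ventricular markers, which include Myl2, had a median of -0.46 (interval -2.02 to 0.10).

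The matrix list, higher in d/d heart, had a median of -0.59 in muscle (interval -0.85 to -0.43), with 34 of 37 members below 0 and 6 at least 2-fold lower. Col1a1 was 2.73-fold lower (1.14-fold on its other probe set, at 138 against 156), Col1a2 2.28-fold, and fibronectin, Fn1, read 120 against 298. Fibroblast markers had a median of -0.53, with 14 of 14 below 0, and Pi16 was 3.14-fold lower. Macrophage markers had a median of -0.55, with 16 of 17 below 0, and Cd163 was 2.88-fold lower. Cell cycle genes had a median of -0.48 (interval -0.84 to 0.06), the lowest over the settings, which reached -0.08, and lost their position under 5 of 9. The heart failure and fetal program had a median of -0.32 (interval -0.96 to 0.12), with 8 of 21 members above 0, Nppa 4.14-fold lower and Xirp1 2.19-fold. Immediate early genes had a median of -0.34 (interval -0.80 to 0.05), with 5 of 22 at least 2-fold lower, among them Junb, 3.45-fold, Fos, 3.27-fold, and Egr1, 2.83-fold. Cytosolic heat shock proteins had a median of -0.35 (interval -0.66 to -0.20), with 17 of 18 below 0 and Hspb7, a small heat shock protein, 2.88-fold lower.

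Also lower in d/d muscle were Fhl3 at 7.04-fold, the desmosomal gene Dsp at 6.83-fold (1.71-fold on its other probe set), Ecrg4 at 6.22-fold, Evc2 at 5.99-fold, Angptl4 at 5.27-fold, 5430401H09Rik at 5.13-fold and Mucl1 at 4.67-fold. Nppb was at least 5.29-fold lower, Anks1 at least 5.95-fold and the collagen hydroxylase gene P3h2 at least 5.09-fold. Pdk4, a kinase that inhibits pyruvate dehydrogenase, read 800 in d/d and 2827 in f/f muscle, 3.53-fold lower, and Ucp3 was 2.93-fold lower. The fatty acid list as a whole had a median of 0.02, with 3 of 29 at least 2-fold lower.

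Genes higher in d/d muscle differed by less and were mostly near the floor. Hrct1 was 4.80-fold higher, at 47.2 against 9.85, the scavenger receptor Stab2 3.80-fold, Chst11 3.56-fold, Abhd8 3.52-fold and C1qtnf4 3.40-fold. Gdpd3, a phosphodiesterase of lipid metabolism, was the brightest of the 10 and 3.32-fold higher, at 415 against 125. Bcl9, 9630015K15Rik, the glycosyltransferase Mfng and the channel Hcn2 were 3.21-fold, 3.13-fold, 3.07-fold and 3.05-fold higher. Zdhhc12 was at least 5.28-fold higher, 4933427E11Rik at least 4.50-fold and Crb3 at least 4.49-fold (1.72-fold on 1 of its other probe sets). Of the iron genes, the iron exporter Slc40a1 was 2.23-fold higher in muscle and 2.23-fold lower in heart.

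Lists that stood apart on the high side in muscle had small shifts. The NRF2 and glutathione list had a median of 0.14 (interval 0.04 to 0.23), with Gstm1 1.53-fold higher, glycolysis 0.15 (interval -0.09 to 0.24), clock genes 0.19 (interval -0.12 to 0.53), with Per1 2.35-fold higher, and red cell markers 0.34 (interval -0.49 to 0.46), and 0 members of the NRF2 and red cell lists passed 2-fold. Antioxidant enzymes had a median of 0.12 (interval 0.06 to 0.18), with 24 of 31 above 0, and did not stand apart at the 97.3rd percentile, though they did under 2 of 9 settings. Respiratory complexes I to IV had medians of 0.06, 0.01, 0.05 and 0.05, ATP synthase 0.10, the tricarboxylic acid cycle 0.08, mitochondrial biogenesis 0.06 and mitochondrial chaperones -0.10. The integrated stress response list had a median of 0.10 (interval -0.23 to 0.37), with Ddit4 2.78-fold higher and Atf3 2.99-fold lower. Skeletal muscle markers and fast fibre genes both had a median of 0.11, with 0 members past 2-fold, though Myh2, the myosin of 2A fibres, was 1.48-fold lower.

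Further lists that did not stand apart in muscle were p53 and cell death (-0.0047), adult cardiac genes (-0.03), calcium handling (0.10), atrophy genes (0.11), muscle regeneration (0.17), interferon-responsive genes (-0.04) and iron and haem (0.04). The same held for markers of lymphocytes (-0.15), neutrophils (-0.17), endothelium (0.09), smooth muscle (0.08), adipocytes (-0.05), nerve (-0.06) and atria (-0.04), and for ribosomal protein genes (0.10). The regeneration list and the iron and haem list each stood apart under 2 of 9 settings, the latter with a median of up to 0.24, and neutrophil markers under 1 of 8. Housekeeping genes had a median of -0.08, which was 0.07 with the median over a gene's probe sets.

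Of 14256 genes measured in muscle, 376 were at least 2-fold higher in d/d and 463 at least 2-fold lower, 207 and 211 of them as lower bounds, and at 3-fold 46 and 69. With the floor at the 60th percentile, 56 and 107 genes passed 2-fold. Of 43 lists, 4 stood apart on the high side and 10 on the low side, and the position of the cell cycle list was lost under 5 of 9 settings, those of the glycolysis, clock and ventricular lists under 3 of 9, of the red cell list under 2 of 7 and of the NRF2 list under 1 of 9. The share past 2-fold depended on signal among genes above the floor on both arrays of a tissue, which leaves out the lower bounds. With mean signals up to 18.95, 10.1% passed 2-fold in heart and 9.38% in muscle, among those of 52.1 to 194 5.48% and 1.34%, and above that 121 of 2881 genes and 26 of 2836.

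**Figure D2:**
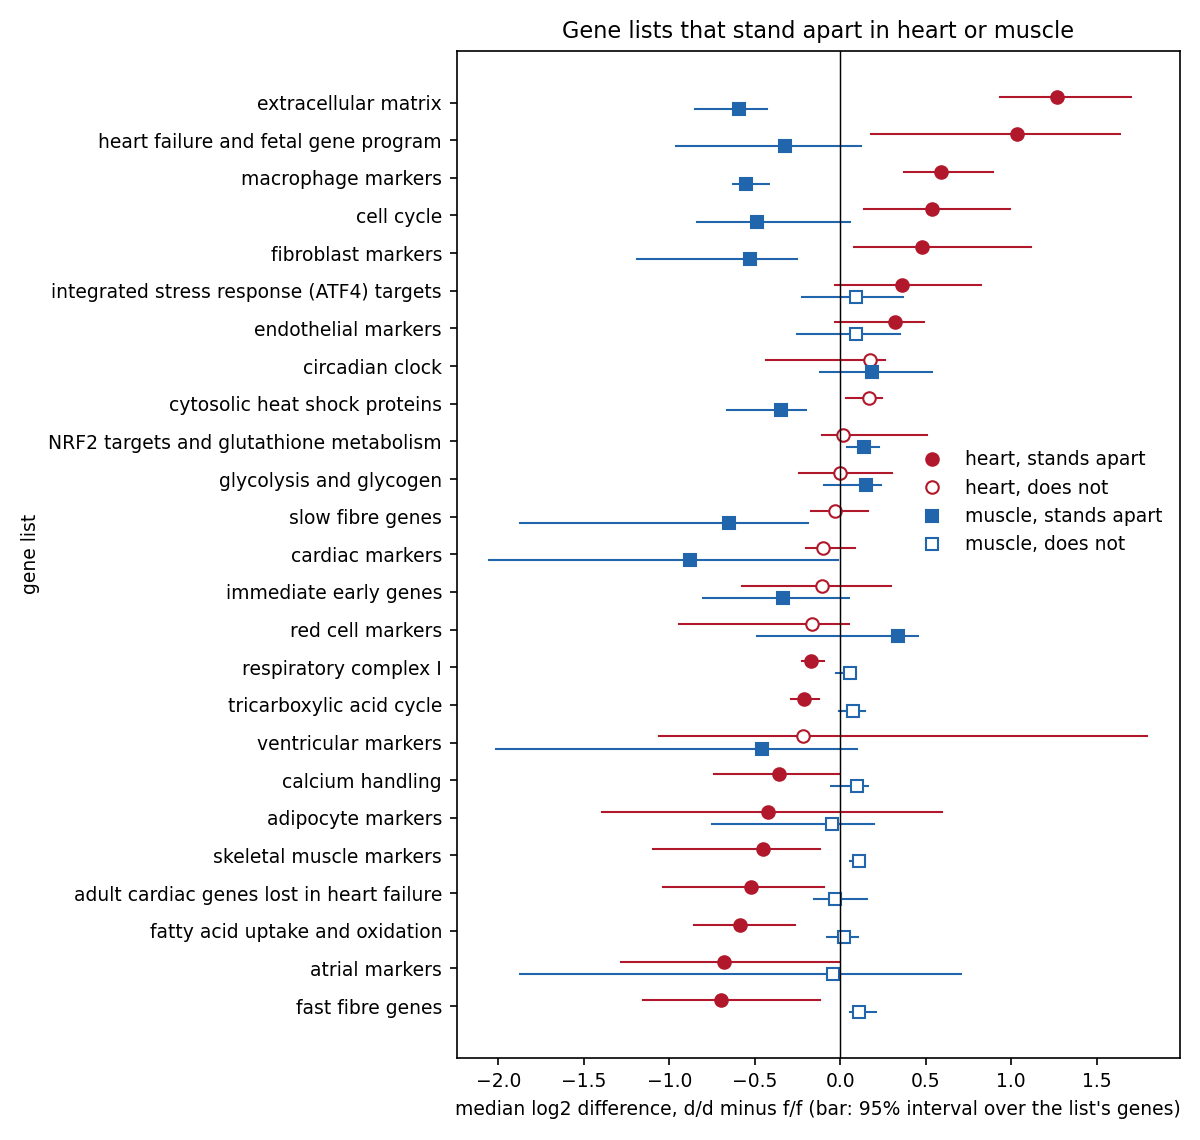
Median log2 difference, d/d minus f/f, of each list that stood apart in heart or muscle, with bars for the 95% interval over the list's genes, heart as circles and muscle as squares, and filled symbols for lists that stood apart. The matrix list lies at 1.27 in heart and -0.59 in muscle.

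The heart and muscle differences were compared gene by gene. The measured fold changes of the tissues were nearly uncorrelated across the 10538 genes above the floor on all 4 arrays. The Pearson correlation was -0.0606 (bootstrap interval -0.0871 to -0.0349) and the Spearman correlation -0.0424, genes not being independent replicates. Measurement error weakens such a correlation. In muscle the SD of the differences across genes was 0.4342, against 0.3996 between probe sets of a gene, and in heart 0.5558 against 0.3882. With 1 array per group, the correlation therefore cannot decide whether the responses of the tissues are unrelated. Genes lower in both tissues numbered 45, against 16.7 expected for independent lists, and genes higher in heart and lower in muscle numbered 50, against 15.9. Genes higher in both numbered 14, against 11.9, and genes lower in heart and higher in muscle 17, against 12.5. The 2 comparisons share no array. The expected numbers take no account of signal level, although genes of low signal passed 2-fold more often in both tissues.

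Among genes above the floor on all 4 arrays, with all measured probe sets on the same side in each tissue, the 10 with the largest shared difference were lower in d/d. Retnla, a resistin-like secreted protein, was 5.30-fold lower in heart and 4.53-fold in muscle. The immediate early gene Fos was 4.64-fold and 3.27-fold lower, Angptl4 3.23-fold and 5.27-fold, and Ucp3 13.5-fold and 2.93-fold. Misp3, the guanylate-binding protein gene Gbp6, the glycerol-3-phosphate acyltransferase Gpat3, the haemoglobin scavenger receptor Cd163, the mitochondrial glutamate carrier Slc25a22 and adiponectin, Adipoq, were 2.46-fold to 4.47-fold lower in heart and 2.30-fold to 3.14-fold lower in muscle, with the other probe set of Gbp6 at 1.79-fold and 1.85-fold. Pdk4, chosen for heart after its values were seen, was 2.24-fold lower there.

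Genes that differed in opposite directions were led by Ecrg4, 6.10-fold higher in d/d heart and 6.22-fold lower in d/d muscle (on its dimmer probe sets 2.67-fold and 2.36-fold, and 1.04-fold and 1.40-fold), and Cilp, 15.5-fold higher and 3.83-fold lower. Cpxm2, a carboxypeptidase-like gene, was 2.86-fold higher and 2.77-fold lower (2.63-fold and 1.06-fold on its other probe set), and Col1a1 3.08-fold higher and 2.73-fold lower (1.62-fold and 1.14-fold). Bcl9 went the other way, 2.80-fold lower in heart (1.27-fold on its other probe set, near the floor) and 3.21-fold higher in muscle. In all, 67 genes passed 2-fold in opposite directions and 59 in the same direction. Over the matrix list the heart difference exceeded the muscle difference in 36 of 37 genes, by a median of 1.91 (interval 1.32 to 2.35). With 4 arrays and 4 groups, the difference between the tissues has no test.

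**Figure D3:**
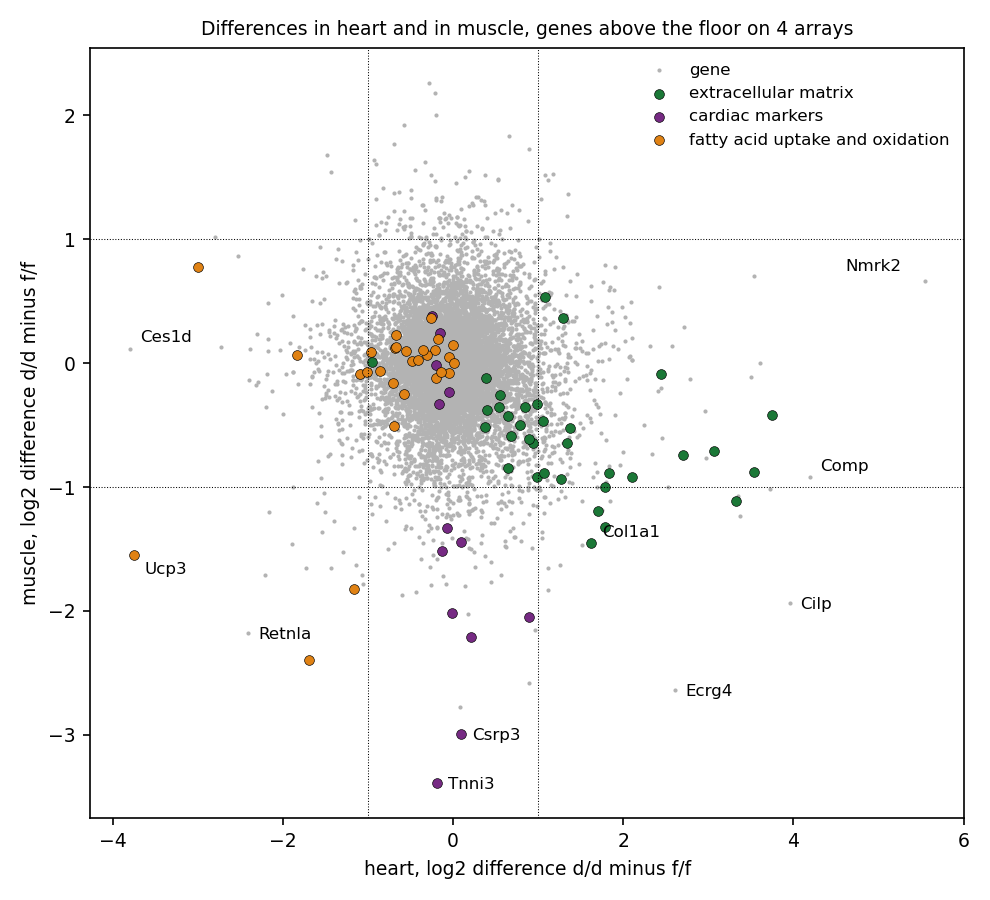
Log2 difference d/d minus f/f in heart (x axis) against that in muscle (y axis) for the 10538 genes above the floor on all 4 arrays, 1 point per gene, with 3 lists coloured and dotted lines at 2-fold. Matrix genes lie to the right and mostly below 0, cardiac markers extend downward, to -3.39 for Tnni3, and Ucp3 lies low on both axes.

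Averaged over heart and muscle, the limma fit called 0 of 13497 genes at an adjusted p of 0.05, and 570 genes had an unadjusted p under 0.05, where 675 would by chance. Retnla had the smallest p, 0.000187, with a mean log2 difference of -2.29 (SE 0.26), lower in both tissues, and an adjusted p of 0.9998. With an intensity trend in the fit, the only alternative with a call, Retnla had an adjusted p of 0.0442, and over the other alternatives the smallest adjusted p of any gene lay between 0.146 and 0.9999.

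The contrast between the tissues gave a check on the tissue labels. In f/f mice cardiac markers had a median log2 difference of 5.13, heart minus muscle, with 19 of 20 at least 2-fold higher in heart, and skeletal muscle markers a median of -8.73, with 20 of 20 lower in heart. In d/d mice the medians were 5.68 and -9.47. Fatty acid genes were higher in heart, with a median of 0.89 in f/f (interval 0.57 to 1.19) and 0.38 in d/d (interval 0.15 to 0.60). Matrix genes differed by -0.01 between the tissues in f/f and by 1.497 in d/d (interval 1.14 to 2.13), and macrophage markers by 0.71 and 1.96. Glycolysis genes went both ways: the median was -0.95 in f/f (interval -1.30 to 0.50) and -1.13 in d/d (interval -1.47 to 0.94), with 13 and 15 of 27 at least 2-fold lower in heart and 7 at least 2-fold higher in each.

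Of the genes measured in f/f, 1741 were at least 2-fold higher in heart and 1192 at least 2-fold lower, and in d/d 2134 and 1485. These counts were 3019 and 2377 in f/f and 3210 and 2868 in d/d with the floor at the 20th percentile, where signals near background enter.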

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

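All tests of explanations in this part were chosen only after the result was seen. Several genes and lists had effects in opposite directions in heart and muscle, and those differences between the tissues were not tested, since each tissue has 1 array per genotype. The heart difference less the muscle difference, on the log2 scale, was 5.24 for Ecrg4, 5.89 for Cilp, 2.98 for Cpxm2, 3.07 for Col1a1 and -3.16 for Bcl9. The median over a list was 1.91 for the matrix, 1.55 for the heart failure and fetal program, 1.13 for macrophage markers, 0.95 for fibroblast markers and 0.88 for the cell cycle, whose position in muscle was lost under 5 of 9 settings. Outside the gene probe sets, the control probe set for the B1 repeat read 3567.5 in d/d heart and 2038.9 in f/f heart, a ratio of 1.75, against 287.63 and 352.01 in muscle. Other controls were also higher on the d/d heart array, the 3 probe sets for the small ribosomal RNA by 1.82-fold, 2.58-fold and 1.64-fold and the 45 spike-in probe sets by a median ratio of 1.229, against 0.9285 in muscle.

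For the cardiac transcripts lower in d/d muscle than in f/f muscle, heart RNA in the f/f muscle sample in a single share, set by Tnni3 and Mybpc3, would bring all abundant heart transcripts, yet 47.1% of 17 other such genes lay below the level that share needs by more than 2 SD of the difference between probe sets. Another 8 of the 17, among them Tnnt2, Myh6, Nppa and Dsp, were at or above that level. A single share would bring all 17 genes together. Yet Myl7 and Ryr2, at 2193 and 1812 in f/f heart, were at the floor of 7.51 in f/f muscle. The values argue against that share for the whole pattern, these 8 genes included. Whether a smaller share added part of their signal was not tested. At the higher share heart RNA reached at most 4.93% of the difference of Csrp3 or Myoz2. Fewer slow fibres would lower all slow fibre genes by about as much. The 4 that are not 2-fold higher in heart had a median of -0.085, with values from -0.45 for Tpm3 to 0.07 for Mb. The 10 other slow fibre genes had a median of -1.045. These values lean against fewer slow fibres, but 4 genes are too few to decide, so that explanation stays open. The genotype is open and untested.

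Matrix genes were higher in d/d heart than in f/f heart. A larger share of fibroblasts alone would raise their other markers alike. The 9 fibroblast markers that are not matrix genes had a median of 0.24 (interval -0.08 to 0.90), below the matrix interval of 0.93 to 1.70. The intervals nearly meet, so this argues only weakly against that explanation. After quantile normalization or removal of the trend the lowest median of the matrix list was 1.30, which argues against a trend with level. Both methods assume a common overall signal of the arrays, so they cannot decide on an offset in scaling. Such an offset would move all genes alike, yet the matched random lists had a median of -0.02 and 0 of 10000 reached the matrix median. These values argue against an offset as the source of the list's position, while the absolute size of its median could still include one. The 45 spike-in probe sets had a median d/d to f/f ratio of 1.229 in heart. More transcript per fibroblast, other cells and the genotype remain open and untested.

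More genes were lower in both d/d tissues than independent lists would share, at 45 against 16.7. The excess was not particular to a shared fall, since genes higher in heart and lower in muscle numbered 50 against 15.9. The expected numbers also take no account of signal level. Less fat in both d/d samples could lower Adipoq and Retnla, and the adipocyte markers had a median of -0.0497 in muscle, with an interval of -0.75 to 0.20 that leaves it open. A different time of day could act in both tissues, and the clock genes' differences had a Spearman correlation of 0.0686 across 17 genes, which leaves it open too. The genotype is an untested alternative to both.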

How the results depend on the processing

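The floor at the 75th percentile and the counts without genes at least 8-fold higher in the other tissue were chosen after seeing the data. With the floor at the 20th percentile, where signals near background enter, 1497 genes were at least 2-fold higher and 1921 lower in d/d heart, 1663 and 1766 in d/d muscle, 3019 and 2377 in heart against muscle in f/f, and 3210 and 2868 in d/d. There, 582 genes passed 2-fold in opposite directions in the tissues and 593 in the same direction, and the correlation across genes was -0.0258. With the floor at the 60th percentile the counts were 320 and 249 in heart and 56 and 107 in muscle, with 24 opposite and 19 in the same direction. At the 75th they were 191 and 123 in heart, 15 and 43 in muscle, 681 and 603 for the tissues in f/f and 931 and 720 in d/d, with 13 opposite, 6 in the same direction and a correlation of -0.0986. A higher floor leaves fewer genes measured by construction. At 3-fold the counts were 149 and 112 in heart and 46 and 69 in muscle. An intensity trend in the limma fit gave 1 call, Retnla, where the fit without it gave 0. Some values turned direction, and the cause was not tested. At the 75th percentile floor the cell cycle list had a median of -0.046 in heart, and muscle regeneration genes differed by 0.33 between heart and muscle in f/f. With quantile normalization the heart difference less the muscle difference of ribosomal protein genes was 0.0022. With the median over a gene's probe sets, Bad was -0.0054, Rrm2 0.45 and Runx1 -0.42 in muscle, and Cacnb1 was -0.18, Mcm5 -0.60 and Ncam1 -0.53 in heart. Without probe sets that can share sequence, Bad was -1.13, Hspa1b 0.058, Rrm2 0.66 and Runx1 -0.67 in muscle, and Mcm5 was -0.91, Ncam1 -1.01 and Pi16 -0.042 in heart. Of the values of single named genes over the alternatives, 2601 kept their direction and their side of 2-fold or stayed within the spread between probe sets, 192 came under 2-fold in the same direction and 157 moved by more than that spread. Of the list medians, 1184 kept sign and call, 41 lost the call, 31 gained it, and 90, all of lists that did not stand apart, changed sign without a call. Of the heart differences less the muscle differences of lists, 312 kept their sign within the main interval and 20 changed sign within it. Of the lists that did not stand apart, 9 of 27 in heart and 20 of 29 in muscle had medians of either sign over the settings. Signal over background limits what can be said of genes near the floor. No paired analysis was possible because each group has 1 array, beyond the limma fit with tissue as a block.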

Other observations

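No tests were added in this part, and each gene was taken by the naming rule in heart or in muscle. The mitochondrial biogenesis list did not stand apart in either tissue, except in heart with the median over a gene's probe sets, and its members named here differed by less than 2-fold on the probe sets that represent them. Ppargc1b, a coactivator of mitochondrial gene expression, was 1.73-fold lower in d/d heart and 1.75-fold lower in d/d muscle, Esrrg, a nuclear receptor, 1.45-fold and 1.63-fold lower, and Ppara 1.75-fold and 1.73-fold lower. Ppargc1a differed in direction, 1.80-fold lower in heart (1.17-fold to 1.44-fold on its other probe sets) and 1.36-fold higher in muscle. Ddit4, a stress-induced inhibitor of mTOR signalling, was 2.17-fold higher in heart and 2.78-fold higher in muscle. The clock gene Per2 was 1.74-fold and 1.72-fold higher (1.05-fold lower in heart on a dimmer probe set), and Per1 1.71-fold and 2.35-fold. The clock list as a whole did not move together. Of its 17 genes, 4 were higher in heart and lower in muscle, and 7 were lower in heart and higher in muscle.

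In heart, Hamp, which encodes the iron-regulating peptide hepcidin, was 3.90-fold lower and Uros, an enzyme of haem synthesis, 2.08-fold lower. The glycolytic gene Pfkp was 2.27-fold higher and the phosphorylase kinase subunit Phkg1 4.53-fold lower (1.86-fold on its other probe set). Pdgfrb, a marker of pericytes, was 2.35-fold higher in heart (1.73-fold on its other probe set) and 1.23-fold higher in muscle. Abcc9 of the same list was 1.75-fold lower in heart (2.14-fold and 2.33-fold on its other probe sets). That list had 7 of 12 members above 0 in heart and did not stand apart. The death regulators Bid and Bcl2 were 2.43-fold and 2.39-fold higher in heart, with 1.01-fold to 3.42-fold on the other probe sets of Bcl2. Bcl2l11 of the same list was 1.998-fold lower, with 1.22-fold to 3.81-fold on its other probe sets.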
